A study of Homo sapiens with 30 samples.

How the data were processed

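Gene expression was measured in peripheral blood of patients with relapsed or refractory neuroblastoma, a childhood tumour of the sympathetic nervous system. The patients took part in a randomised phase II trial of metaiodobenzylguanidine labelled with iodine-131 (MIBG), a noradrenaline analogue that carries radiation into cells with the noradrenaline transporter. One arm received MIBG alone, a second arm MIBG with vincristine and irinotecan (named MIBG+irinotecan here), and the third arm MIBG with vorinostat, an inhibitor of histone deacetylases. Irinotecan is a topoisomerase I inhibitor and vincristine blocks microtubules. Each arm had 5 libraries from day 0, before treatment, and 5 from day 3, 72 h later, which made 30 libraries in 6 groups.

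Per the labels' protocols, RNA came from blood in PAXgene tubes, libraries were made with the QuantSeq FWD 3′ kit with molecular identifiers (UMIs) and a block against globin transcripts, and single-end reads of 85 bp were sequenced. The kit reads the 3′ end of polyadenylated transcripts on the sense strand, so a count reflects a transcript's number and not its length. The authors deposited 1 table of read counts per arm, with 59385 rows and 1 column per library, and the values were whole numbers that were not normalised. Per the submitters' processing notes, the build was GRCh38 (hg38) and the tools were FastQC, STAR, SAMtools, featureCounts and DESeq2. Their versions and roles, the annotation, the strand setting and the use made of the UMIs are not given in the sources used here. Counts that still held PCR copies would make the counting error look smaller than it is, and counts without strand would mix overlapping genes on opposite strands. All 30 count columns had a group, and 0 columns were without one. Rows named by an Ensembl ID and not by a symbol (657 rows, 0.00616% of the counts) stayed in the library sizes and in the tests, and were not named.

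Counts per library summed to between 2209233 and 3803160, with 12009 to 16692 genes detected. At these depths a gene near the filter on low counts is read only a few times per library, so single low genes carry a wide error. Levels are given as counts scaled to library size (CPM). No pair of libraries within a group differed by as little as sampling noise: the lowest chi-square per degree of freedom in a group ran from 20.6 to 44.3. Each library was therefore counted as 1 sample.

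The day was read from the column names, which end in 1 or 2 after a number shared by 2 columns. The name ending in 1 was taken as day 0 and the name ending in 2 as day 3, because the labels do not state the code. If the code ran the other way, every direction of a change below would be reversed and the numbers of genes called for changes would not change, while the tests of levels at day 0 or day 3 would be of the other libraries. The shared number was taken to mark the donor. As a check, each library's deviation from its group's mean was correlated with that of its partner. Over 39 genes with common inherited differences in expression, r was 0.547 to 0.941 in the 15 pairs. Between libraries that were not partners r reached 0.583 with MIBG alone, 0.737 with irinotecan and 0.922 with vorinostat. The list behind these genes held sex-linked genes, so donors of the same sex can correlate too. Of the day 3 libraries 15 of 15 correlated best with their own partner within the arm, and of the day 0 libraries 14 of 15. Over all 13286 tested genes r was 0.0369 to 0.294, above 0.1 in 13 of the 15 pairs, and 13 of 15 day 3 and 14 of 15 day 0 libraries matched their own partner best. Pairing was decided from this check before the fits were compared. The block had been planned with the replicate number of the labels, and the number shared by the columns took its place once the columns were read. Libraries are named replicate 1 to 5 by the order of that number within an arm, and replicate 1 of day 0 and of day 3 are then 1 donor. Pairing was not part of the main fits, which were fixed before the data were examined. Blocked values are given where they changed a call of a list or of a gene described below. Replicates are separate donors, so the p-values cover differences between people.

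Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by the trimmed mean of M values (TMM). Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 10722 genes for MIBG alone, 10251 for MIBG+irinotecan, 10790 for MIBG+vorinostat and 13286 for fits of all 30 libraries. Day 3 was compared with day 0 by the quasi-likelihood test (glmQLFit and glmQLFTest), per arm on its 10 libraries and over the 30 libraries with arm as a covariate. The change in 1 arm was compared with that in another as a contrast of 6 group means, and the same fit gave an F test of the 3 arms at day 0. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 are said to have passed, risen or fallen. Log2 fold changes are edgeR's, with their standard errors (SE), and levels are TMM-scaled CPM as mean ± SD over the 5 libraries of a group. Totals and shares of counts were compared by two-sided exact permutation tests of 5 against 5 libraries, where the smallest possible p is 0.0079, and within donors by exact tests that flip the signs of the changes.

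Before the data were examined, 25 gene lists were written from general knowledge of blood cell markers and of the treatments: p53 and radiation response, a blood biodosimetry panel of 12 genes, B cell, plasma cell, T cell, natural killer (NK) and cytotoxic lymphocyte, monocyte, mature neutrophil, neutrophil granule, eosinophil and basophil, dendritic cell, erythroid, globin, platelet, interferon response, proliferation, NF-kappaB and inflammation, immediate early and heat shock, glucocorticoid response, histone deacetylase (HDAC) and HDAC inhibitor response, DNA repair and topoisomerase, neuroblastoma, stem and progenitor, mitochondrially encoded, and ribosomal protein. The panel lies inside the p53 list. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. The same test with a correlation estimated from the data, and fry, which asks whether a list's genes move one way without comparing them with other genes, were alternatives. Blood is a mixture, so markers of a cell type describe genes and do not count cells.

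Genes named in the text were chosen by a rule fixed in advance. It took the 12 panel genes, the 8 genes per direction with the largest fold changes among those that passed at a mean of at least 4 CPM (10 per direction for all arms together), and the 2 members with the smallest p of each list that was called. For differences between arms, where no gene passed, it took the 3 genes per direction with the smallest p, and for day 0, where the F test has no direction, the 6 genes with the smallest p. XIST, TSIX, genes of the Y chromosome, HLA and KIR genes, variable segments of antigen receptors, LILRA3, GSTM1 and features without a symbol were left out. Other genes are said to be chosen after their values were seen. Coordinates are those of GENCODE release 29 on GRCh38, matched by symbol.

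Alternatives fixed in advance were DESeq2's median-of-ratios factors, no filter, a stricter filter at a mean of 4 CPM, DESeq2 1.42.0, limma voom with quality weights, the fit without globin, mitochondrial and ribosomal protein genes, a block for the donor, 1 fit over 30 libraries for each arm, and leaving out each library in turn. The fits without the 3 libraries that stood farthest apart in globin counts or scaling, the list tests of differences between arms, and the block joined with an estimated correlation were chosen after seeing the data.

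The tests were run on simulated counts drawn from the real means, library sizes and spread, with 200 genes changed. Means and spread were those of the fit of all 30 libraries, so an arm's own spread was not simulated. Shares are of all 50 genes changed by a fold, also those that the filter left out. In the MIBG alone setting 39 of the 50 genes changed 16-fold were tested, and 37 were recovered. In the MIBG alone setting 2, 28, 62 and 74% of genes changed 2, 4, 8 and 16-fold were recovered. For MIBG+irinotecan these were 0, 30, 54 and 74%, for MIBG+vorinostat 0, 36, 58 and 66%, for all arms together 20, 80, 82 and 86%, and for the difference of MIBG+irinotecan and MIBG alone 0, 18, 36 and 58%. Unchanged genes called numbered 2, 2, 5, 7 and 4 in these fits. DESeq2 called 109 genes in the MIBG+irinotecan setting, 17 of them unchanged, against 81 and 2 by edgeR. In 21 simulations on 13286 genes of the MIBG+irinotecan setting, 42 of 42 lists moved 2-fold (T cell and monocyte, 2 per simulation) were called, as were 2 of the 439 other lists, both in 1 simulation. Genes were simulated independently, so the simulation cannot show how correlation between genes affects camera. In the real libraries, splits by days other than the real ones called a median of 9 lists for MIBG alone. The medians were 8 for irinotecan, 8 for vorinostat and 9 for all arms. A call by camera with its preset correlation was thus frequent under other day labels, and its adjusted p is not to be taken at face value. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.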

Results

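Blood was drawn on day 0 and on day 3 in each of 3 treatment arms of a trial of radioactive MIBG in neuroblastoma, with 5 libraries per arm and day. Counting the 3′ ends of transcripts in whole blood gives a level for each gene summed over all white cells, platelets and immature red cells. Total counts per library ranged from 2209233 to 3803160. Their means were 3411000 ± 237800 (SD, n = 5) at day 0 and 2778000 ± 406100 (SD, n = 5) at day 3 in the MIBG alone arm. They were 3151000 ± 357800 and 2799000 ± 411600 (SD, n = 5 each) with irinotecan, and 3401000 ± 282700 and 2865000 ± 437300 (SD, n = 5 each) with vorinostat. The share of counts on globin genes varied widely in spite of the globin block, from 1.88% to 38.06%. With irinotecan it was 15.9 ± 6.78% (SD, n = 5) at day 0 and 6.17 ± 4.74% at day 3, by an exact permutation test p = 0.0317 and adjusted p = 0.133 over 21 such tests. It was 6.08 ± 5.17% and 11.8 ± 9.67% with MIBG alone (SD, n = 5 per day, exact p = 0.357), and 7.61 ± 6.99% and 12.7 ± 14.4% with vorinostat (exact p = 0.563). The count of HBB, the adult beta globin, per count of HBA2, an alpha globin, was lower at day 3 in each arm. Its mean went from 2.39 to 1.12 with MIBG alone, from 1.99 to 1.00 with irinotecan and from 2.69 to 0.794 with vorinostat. In MIBG alone day 3 replicate 5 the ratio was 0.041, against 1.02 to 1.80 in the rest of that group. That library weighs heavily on the mean log2 ratio of its group. On the log2 ratio the exact permutation p-values were 0.0159, 0.00794 and 0.00794, and none passed after adjustment (0.111, 0.0834 and 0.0834). Those tests leave the pairing out. Within donors the ratio was lower at day 3 in 15 of 15, with an exact sign-flip p = 6.1e-05 over the arms (adjusted p = 0.000427 over 7 measures). The total count was lower in 13 of 15 donors (exact sign-flip p = 0.000244, adjusted p = 0.000854). In 1 arm of 5 pairs the exact sign-flip test cannot go below p = 0.0625. The paired tests were chosen after the ratios were seen. HBA2 shares sequence with HBA1, so its own count is uncertain. No gene of the neuroblastoma list (0 of 17) had enough counts to be tested. The summed counts of its 17 genes per group lay between 26 and 76, or 1.86 to 4.47 CPM.

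The first comparison asked how blood transcripts changed over 3 days after MIBG alone. CDKN1A, the p53 target that encodes the cell cycle inhibitor p21, rose from 23.4 ± 8.60 to 296 ± 101 CPM (SD, n = 5 per day). This was a 12.6-fold rise (log2 fold change 3.66, SE 0.37, edgeR adjusted p = 0.000955), with higher values in 5 of 5 donors. The directions take the first draw as day 0. It was the only gene of 10722 that passed by edgeR, and passed without any 1 library (highest adjusted p = 0.00961). Before adjustment 1621 genes had p under 0.05. With the donor as a block 381 genes passed, 217 higher and 164 lower at day 3, while DESeq2 called 314 and voom 37 without the block.

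Other genes of the radiation panel stood higher at day 3 with MIBG alone, and passed with the donor block. FDXR, a mitochondrial reductase induced by p53, was 8.13-fold higher (log2 3.02, adjusted p = 0.0792, blocked 0.0147). DDB2 and XPC, which recognise damage in nucleotide excision repair, were 3.77-fold and 3.28-fold higher (adjusted p = 0.137 and 0.166, blocked 0.0147 and 0.00947). BBC3, which encodes the apoptosis protein PUMA, was 3.37-fold higher (adjusted p = 0.137, blocked 0.0112), and the nuclease gene AEN 4.54-fold higher (adjusted p = 0.115, blocked 0.0147). ZMAT3, an RNA-binding p53 target, was 2.22-fold higher (adjusted p = 0.166, blocked 0.0383). MDM2, BAX, GADD45A, PHPT1 and PCNA passed neither way, with adjusted p of 0.175, 0.33, 0.646, 0.884 and 0.989. The panel as a list was called higher by camera (median log2 change 1.43, adjusted p = 8.16e-11; adjusted p = 0.00109 with an estimated correlation and 0.0678 when the block was added to that). Of its 12 genes 1 passed over all genes tested (7 with the block) and 8 when adjusted over the list alone. The p53 list, which holds the panel, was called higher too (median 0.81, adjusted p = 8.16e-11, adjusted p = 0.00109 with an estimated correlation, 0.0678 with the block added), with 1 of 33 genes past the test (8 with the block) and 12 adjusted over the list alone.

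Platelet genes stood higher in 24 of 24 members with MIBG alone, and lymphocyte genes stood lower. The platelet list had a median log2 change of 1.77 (camera adjusted p = 2.07e-14, adjusted p = 0.137 with an estimated correlation). None of its genes passed over all genes (11 with the block), and 16 were higher when adjusted over the list alone. MYL9, a myosin light chain, went from 3.46 to 54.7 CPM (adjusted p = 0.0792, blocked 0.0185). ITGB3, a subunit of the fibrinogen receptor, went from 21.4 to 124 CPM (adjusted p = 0.0792, blocked 0.00867). T cell genes had a median of -1.12 (camera adjusted p = 3.69e-06, adjusted p = 0.419 with an estimated correlation), with 0 of 25 past the test and 6 lower adjusted over the list alone, and with the block 4 and 14. The T cell receptor subunit CD3G had a log2 change of -1.83 (adjusted p = 0.166, blocked 0.0254). B cell genes had a median of -1.76, lower in 20 of 20 (camera adjusted p = 3.13e-05, adjusted p = 0.45 with an estimated correlation), with 0 genes past the test over all genes or over the list alone. With the donor block 8 B cell genes were lower over all genes and 16 over the list alone. NK genes had a median of -0.72 (camera adjusted p = 0.00053, adjusted p = 0.321 with an estimated correlation), with 0 of 20 past the test and 1 lower adjusted over the list alone, and with the block 2 and 5. The NK receptor KLRF1 had a log2 change of -2.87 (adjusted p = 0.166, blocked 0.0147).

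Camera called 15 of 23 lists with MIBG alone, and 2 of these, panel and p53, held with an estimated correlation. Proliferation (median -1.16, 0 of 16 genes past the test, 1 with the block) and ribosomal protein genes (-0.96, 0 of 23, 4 with the block) were called lower. So was the DNA repair and topoisomerase list (-0.54, 0 of 25 either way). The camera adjusted p were 0.000146, 3.34e-06 and 0.0294 in that order. With an estimated correlation their adjusted p were 0.268, 0.42 and 0.137. Adjusted over the list alone 4 ribosomal protein genes passed, and 16 with the block. Mature neutrophil (0.78, 0 of 20 genes past the test, 5 with the block), interferon (1.06, 0 of 24, 2 with the block), mitochondrially encoded (0.59, 0 of 13 either way), HDAC (0.60, 1 of 17, 3 with the block), monocyte (0.40, 0 of 17 either way) and NF-kappaB (0.30, 0 of 12, with the block 1 lower) genes were called higher. Their adjusted p were 5.61e-06, 0.000277, 0.000478, 0.00496, 0.00746 and 0.0421, and 0.419, 0.508, 0.419, 0.0903, 0.508 and 0.508 with an estimated correlation. The HDAC list shares CDKN1A with the p53 list, and CLU with the platelet list. With the block NF-kappaB was no longer called (0.0797), while the eosinophil and basophil list (0.0355) and the neutrophil granule list (0.0254) were. Without day 0 replicate 5 the number of genes that passed was 5. The monocyte call was lost without day 0 replicate 3 or day 3 replicate 2 (up to 0.0578), the DNA repair call without day 3 replicate 3 (0.0529), and the NF-kappaB call without any of 8 libraries (up to 0.319).

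The second comparison asked the same of MIBG with vincristine and irinotecan. Of 29 erythroid genes, those of immature red cells, 28 fell, while 19 of 20 mature neutrophil genes and 11 of 34 p53 list genes rose and 1 of the p53 list fell. The adjusted p of these lists with an estimated correlation were 0.156, 0.142 and 0.0725. The erythroid list had a median log2 change of -4.53 (camera adjusted p = 1.77e-22, adjusted p = 0.156 with an estimated correlation), and 28 also fell when adjusted over the list alone. SELENBP1, a selenium-binding protein of red cell precursors, went from 1636 ± 968 to 11.0 ± 11.6 CPM (SD, n = 5 per day), 154-fold lower (log2 -7.27, SE 0.74, edgeR adjusted p = 0.000114). AHSP, the chaperone of alpha globin, went from 847 ± 330 to 32.2 ± 9.84 CPM, 26.6-fold lower (adjusted p = 1.8e-05), and EPB42, a protein of the red cell membrane skeleton, was 41.3-fold lower (adjusted p = 4.41e-05). All 3 were lower in 5 of 5 donors. The transporter gene ABCG2 had 453 counts over the day 0 libraries and 0 at day 3, at least 141-fold lower with a floor of 3 counts over the group. TSPAN7 had 361 and 0 counts, at least 113-fold lower by the same floor. IFIT1B, which is in the erythroid list, was 414-fold lower (log2 -8.69, adjusted p = 0.000317), and RAP1GAP and PLEK2 were 216-fold and 93.4-fold lower (adjusted p = 0.000785 and 0.000331). The globin list was called lower (median -2.10, camera adjusted p = 0.000235, adjusted p = 0.373 with an estimated correlation), with 4 of 7 genes past the test and 6 adjusted over the list alone. HBD, the delta globin, was 30.1-fold lower (adjusted p = 0.00042).

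Over all genes, 1755 of 10251 passed with irinotecan, 975 higher and 780 lower. With the donor block 2517 passed, and 1730 passed in both fits. The median log2 change of all tested genes was -0.10. Mature neutrophil genes rose in 19 of 20 members (median 1.78, camera adjusted p = 2.13e-13, adjusted p = 0.142 with an estimated correlation), and in 20 adjusted over the list alone. CXCR1, an interleukin 8 receptor, rose 4.78-fold (adjusted p = 0.000509), and MMP25, a membrane metalloprotease, 4.63-fold from 184 ± 49.4 to 854 ± 101 CPM (SD, n = 5 per day, edgeR adjusted p = 0.000266). Of the 12 panel genes 9 rose, and 9 adjusted over the list alone (median 1.75, camera adjusted p = 1.38e-06, adjusted p = 0.0167 with an estimated correlation, 0.0724 with the block added). CDKN1A rose 7.99-fold from 34.8 ± 22.6 to 279 ± 123 CPM (SD, n = 5 per day, edgeR adjusted p = 0.000788). FDXR rose 10.2-fold from a low and uneven level, 2.38 ± 2.97 to 24.8 ± 13.9 CPM (SD, n = 5 per day). Its edgeR adjusted p was 0.0175, and up to 0.0483 without 1 library. BBC3 rose 4.80-fold, DDB2 4.87-fold, XPC 3.50-fold, ZMAT3 3.22-fold, AEN 3.15-fold and MDM2, the ubiquitin ligase of p53, 2.81-fold. BAX, an apoptosis effector, rose 4.08-fold (adjusted p = 0.0347, blocked 0.054, and up to 0.103 without 1 of 7 libraries). GADD45A, PCNA and PHPT1 had adjusted p of 0.502, 0.616 and 0.668. In the p53 list 11 of 34 genes rose and 1 fell, 13 and 1 adjusted over the list alone (median 0.89, camera adjusted p = 1.76e-05, adjusted p = 0.0725 with an estimated correlation).

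Camera called 13 of 22 lists with irinotecan, and 1, the panel, held with an estimated correlation. Ribosomal protein genes (median -1.18, 9 of 23 fell, 19 with the block, 14 adjusted over the list alone) were called lower at adjusted p = 5.71e-06, which was 0.415 with an estimated correlation. RPL4 and RPL7 fell 3.53-fold and 3.50-fold. NK genes (-1.18, 4 of 21 fell, with the block 8 fell and 1 rose) and monocyte genes (-0.79, 6 of 17 fell) were called lower at 0.0035 and 0.0197, with adjusted p = 0.415 and 0.391 with an estimated correlation. The granzyme gene GZMA fell 6.07-fold (adjusted p = 0.00867), and VCAN and CPVL of the monocyte list 2.78-fold and 3.05-fold. B cell genes (median -2.05, 1 of 19 fell, 0 adjusted over the list alone, 8 and 10 with the block) were called lower at 0.0208 (adjusted p = 0.607 with an estimated correlation). Platelet (1.49, 2 of 25 rose, 14 with the block), interferon (0.70, 2 of 24 rose, 7 with the block), immediate early (0.84, 4 rose and 1 fell of 13) and NF-kappaB (0.73, 4 of 12 rose) genes were called higher, at adjusted p = 0.000235, 0.0197, 0.0197 and 0.0288. These were 0.561, 0.607, 0.142 and 0.285 with an estimated correlation. IL1B, an inflammatory cytokine, rose 3.43-fold (adjusted p = 0.00532), and DUSP1 and IER2, early response genes, 2.53-fold and 2.70-fold. Among the largest rises were H2BC4, a histone gene (24.9-fold, adjusted p = 0.000978), C10orf105 (28.4-fold, adjusted p = 0.00156) and MTND6P11, a copy of a mitochondrial gene (18.9-fold, adjusted p = 0.00221). H2BC4 and MTND6P11 have close copies, and their counts are uncertain. Calls were lost without single libraries for B cell genes (day 0 replicate 2 or 5, day 3 replicate 4, up to 0.145), monocyte genes (day 0 replicate 4, day 3 replicate 3, up to 0.0697), interferon genes (day 0 replicate 4, day 3 replicate 2 or 5, up to 0.208) and NF-kappaB genes (day 0 replicate 1, day 3 replicate 2, up to 0.0547).

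The third comparison covered MIBG with vorinostat. Of 20 B cell genes 12 fell, while 10 of 20 mature neutrophil genes and 8 of 33 p53 list genes rose. With an estimated correlation the B cell and neutrophil lists had an adjusted p = 0.414 each, and the p53 list 0.00477. MS4A1, which encodes the B cell antigen CD20, went from 417 ± 395 to 17.9 ± 9.44 CPM (SD, n = 5 per day), 22.3-fold lower (log2 -4.48, SE 0.81, edgeR adjusted p = 0.00751), and lower in 4 of 5 donors. PAX5, the B lineage transcription factor, was 22.2-fold lower (adjusted p = 0.0174), the adaptor gene BLNK 8.83-fold (adjusted p = 0.00752), the receptor gene TNFRSF13C 17.5-fold (adjusted p = 0.0337) and FCRL2 21.6-fold (adjusted p = 0.0397). Leaving out 1 library ended the call of PAX5 (day 0 replicate 4, 0.0529), of TNFRSF13C (6 of the 10 libraries, up to 0.123) and of FCRL2 (8 of 10, up to 0.106), and not that of MS4A1 or BLNK (up to 0.0209 and 0.0291). Adjusted over the list alone 20 B cell genes fell (median -3.25, camera adjusted p = 3.61e-09, adjusted p = 0.414 with an estimated correlation). FDXR rose 17.8-fold (adjusted p = 0.00379), again from a low level, 2.06 ± 1.33 to 35.6 ± 18.0 CPM (SD, n = 5 per day). CDKN1A rose 11.3-fold from 17.8 ± 4.70 to 193 ± 128 CPM (SD, n = 5 per day, edgeR adjusted p = 0.00316). BBC3 rose 6.93-fold (adjusted p = 0.00288). DDB2, XPC, AEN and ZMAT3 rose 6.23-fold, 4.41-fold, 4.07-fold and 3.42-fold. MDM2 and GADD45A passed with the donor block alone (adjusted p = 0.0516 and 0.0637, blocked 0.0178 and 0.0129), and BAX, PHPT1 and PCNA in neither fit. The panel was called higher (median 1.90, 7 of 12 rose, 10 adjusted over the list alone, camera adjusted p = 1.85e-08, adjusted p = 0.0197 with an estimated correlation, 0.234 with the block added). So was the p53 list (0.96, 8 of 33 rose, 13 adjusted over the list alone, camera adjusted p = 3.59e-08, adjusted p = 0.00477 with an estimated correlation, 0.234 with the block added).

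Over all genes, 1065 of 10790 passed with vorinostat, 662 higher and 403 lower. With the block 1585 passed, and 1015 passed in both fits. Mature neutrophil genes had a median of 1.42 (10 of 20 rose, 16 with the block, 15 adjusted over the list alone, camera adjusted p = 1.54e-08, adjusted p = 0.414 with an estimated correlation). CSF3R, the receptor of granulocyte colony-stimulating factor, rose 4.39-fold from 507 ± 192 to 2164 ± 664 CPM (SD, n = 5 per day, edgeR adjusted p = 0.00642). T cell genes (-0.62, 2 of 26 fell, 1 adjusted over the list alone), NK genes (-0.83, 2 of 21 fell), proliferation genes (-0.68, 1 of 14 fell) and ribosomal protein genes (-0.20, 1 of 23 fell) were called lower at adjusted p = 0.00172, 0.00825, 0.0256 and 0.0127. With an estimated correlation these adjusted p were 0.553, 0.42, 0.414 and 0.596. With the block 7, 5, 2 and 4 of these genes fell, and 10 T cell genes adjusted over the list alone. CD28, a costimulatory receptor of T cells, fell 3.94-fold (adjusted p = 0.00948), GZMA 5.59-fold (adjusted p = 0.00474) and RRM2, a subunit of ribonucleotide reductase, 11.8-fold (adjusted p = 0.0406, and up to 0.127 without 1 of 8 libraries). Mitochondrially encoded (0.96, 1 of 13 rose, 6 with the block) and neutrophil granule genes (1.07, 0 of 9 rose, 1 with the block) were called higher at 0.00941 and 0.0435, with adjusted p = 0.553 and 0.414 with an estimated correlation. The HDAC list, chosen for the target of vorinostat, was not called (median 0.43, 4 rose and 1 fell of 17, camera adjusted p = 0.0664). Camera called 10 of 23 lists, of which panel and p53 held with an estimated correlation, and the block added erythroid (0.00442), eosinophil and basophil (0.0141) and plasma cell (0.0185) lists. Without day 0 replicates 2, 3 or 4, or day 3 replicate 3, 483, 481, 436 and 628 genes passed. List calls were lost for NK and mitochondrial genes without day 3 replicate 5 (0.0567 and 0.0845), proliferation without day 0 replicate 3 (0.1), ribosomal protein genes without day 3 replicate 2 or 4 (up to 0.14) and neutrophil granule genes without any of 5 libraries (up to 0.121). Without day 0 replicate 5, 16 lists were called.

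**Figure D1:**
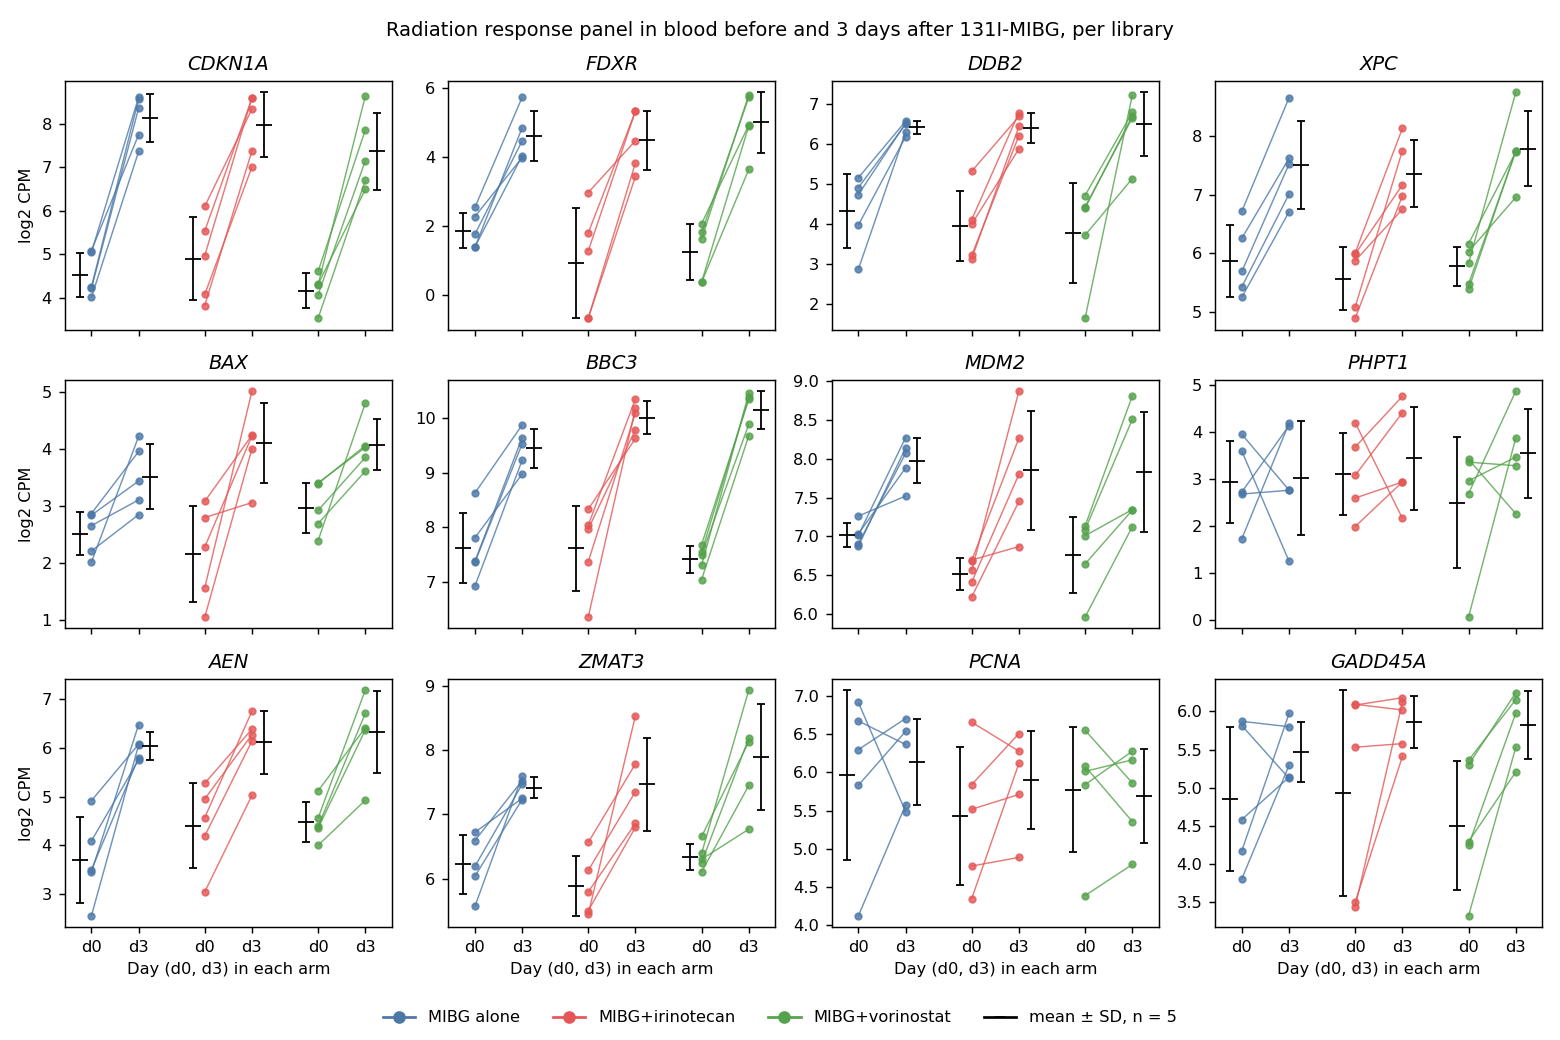
Levels of the 12 panel genes in each library, as log2 CPM on the vertical axis, by arm and day on the horizontal axis, with lines joining the libraries of 1 donor and bars for mean ± SD (n = 5). CDKN1A was higher at day 3 in 15 of 15 donors.

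The fourth comparison took the 3 arms together, with arm as a covariate, for the change averaged over them. CDKN1A rose 10.3-fold (log2 3.37, SE 0.26, edgeR adjusted p = 9.66e-11) and FDXR 11.1-fold (adjusted p = 5.82e-07), each in 15 of 15 donors. The largest rises included other p53 targets. PHLDA3, an inhibitor of AKT, rose 34.5-fold (adjusted p = 1.8e-05), MIR34AHG, the host transcript of the microRNA miR-34a, 26.8-fold (adjusted p = 4.47e-05), and the receptor gene EDA2R 19.9-fold (adjusted p = 1.95e-05). PI3, which encodes the protease inhibitor elafin, rose 10.6-fold (adjusted p = 6.5e-07). JCHAIN, the joining chain of secreted antibodies, fell 12.6-fold in the fit adjusted for arm (adjusted p = 2.78e-06), and RRM2 11.2-fold (adjusted p = 0.000105), each in 15 of 15 donors. Within arms the log2 change of JCHAIN was -2.21 with MIBG alone (adjusted p = 0.175, blocked 0.0092), -5.37 with irinotecan (adjusted p = 0.000331) and -3.66 with vorinostat (adjusted p = 0.00998). In all, 3792 of 13286 genes passed, 1881 higher and 1911 lower. CDKN1A lies on chromosome 6 at 36676460-36687339, FDXR on chromosome 17 at 74862497-74873031, PHLDA3 on chromosome 1 at 201464383-201469237, EDA2R on X at 66595637-66639298, JCHAIN on chromosome 4 at 70655541-70681817, MS4A1 on chromosome 11 at 60455752-60470760 and SELENBP1 on chromosome 1 at 151364302-151372733 (GRCh38). Counts at 3′ ends do not tell exons or introns apart.

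Across the arms, camera called 17 of 24 lists, and 3 held with an estimated correlation: panel, p53, and DNA repair and topoisomerase. The panel (median 1.70, 10 of 12 rose, 10 adjusted over the list alone) and the p53 list (0.75, 22 of 35, 22 adjusted over the list alone) both had a camera adjusted p of 3.22e-12, and adjusted p = 1.16e-05 with an estimated correlation (0.000703 with the block added). The DNA repair and topoisomerase list (-0.50, 9 fell and 1 rose of 28) was called lower at 0.0122. Its adjusted p was 0.0434 with an estimated correlation and 0.11 with the block added. That list also holds genes that are not repair genes, among them the transporter gene ABCG2, which fell (edgeR adjusted p = 0.000672). Mature neutrophil genes (1.35, 16 of 20 rose, 19 adjusted over the list alone) were called higher at 2.76e-12, and platelet genes (1.20, 13 of 25 rose, 14 adjusted over the list alone) at 3.97e-06. With an estimated correlation their adjusted p were 0.148 and 0.372. B cell (-2.32, 17 of 22 fell, 21 adjusted over the list alone), NK (-1.03, 12 of 24 fell), T cell (-0.85, 10 of 27 fell), erythroid (-1.85, 16 of 30 fell, 20 adjusted over the list alone), proliferation (-1.44, 10 of 24 fell) and ribosomal protein genes (-0.82, 15 fell and 1 rose of 23) were called lower. Their adjusted p were 2.46e-06, 3e-05, 0.00204, 1.03e-05, 1.99e-05 and 2.02e-06, and 0.372, 0.185, 0.47, 0.416, 0.153 and 0.372 with an estimated correlation. Interferon (0.73, 7 of 27 rose), mitochondrial (0.71, 7 of 13), immediate early (0.84, 5 rose and 1 fell of 17), eosinophil and basophil (0.98, 2 of 12, with the block 5 and 1 lower), NF-kappaB (0.23, 5 rose and 1 fell of 13) and HDAC genes (0.12, 7 rose and 3 fell of 19) were called higher. Their adjusted p were 0.00684, 0.00684, 0.00712, 0.013, 0.029 and 0.029, and 0.534, 0.468, 0.223, 0.378, 0.378 and 0.112 with an estimated correlation. Several of the lists called across the arms were not called in every arm. Erythroid genes were not called with MIBG alone (median -0.79, camera adjusted p = 0.864) or vorinostat (-1.21, 0.146, blocked 0.00442). Platelet and interferon genes were not called with vorinostat (medians 0.31 and 0.29, camera adjusted p = 0.192 and 0.262). CCR3, the eotaxin receptor, rose 3.09-fold (adjusted p = 9.14e-05), HDAC7 2.80-fold (adjusted p = 6.05e-06) and NRGN of the platelet list 3.85-fold (adjusted p = 0.000303).

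The other 7 lists were not called across the arms. They were plasma cell (median -1.41, adjusted p = 0.0615, blocked 0.0408), dendritic cell (-1.32, 0.155), glucocorticoid response (0.29, 0.173), neutrophil granule (-0.57, 0.463), globin (-0.29, 0.657), stem and progenitor (-0.16, 0.902) and monocyte (0.09, with a mean of -0.05, 0.94). GATA2 is in both the stem and the eosinophil and basophil lists, and CD163 in both the monocyte and the glucocorticoid lists. No list call across the arms was lost without any 1 library.

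**Figure D2:**
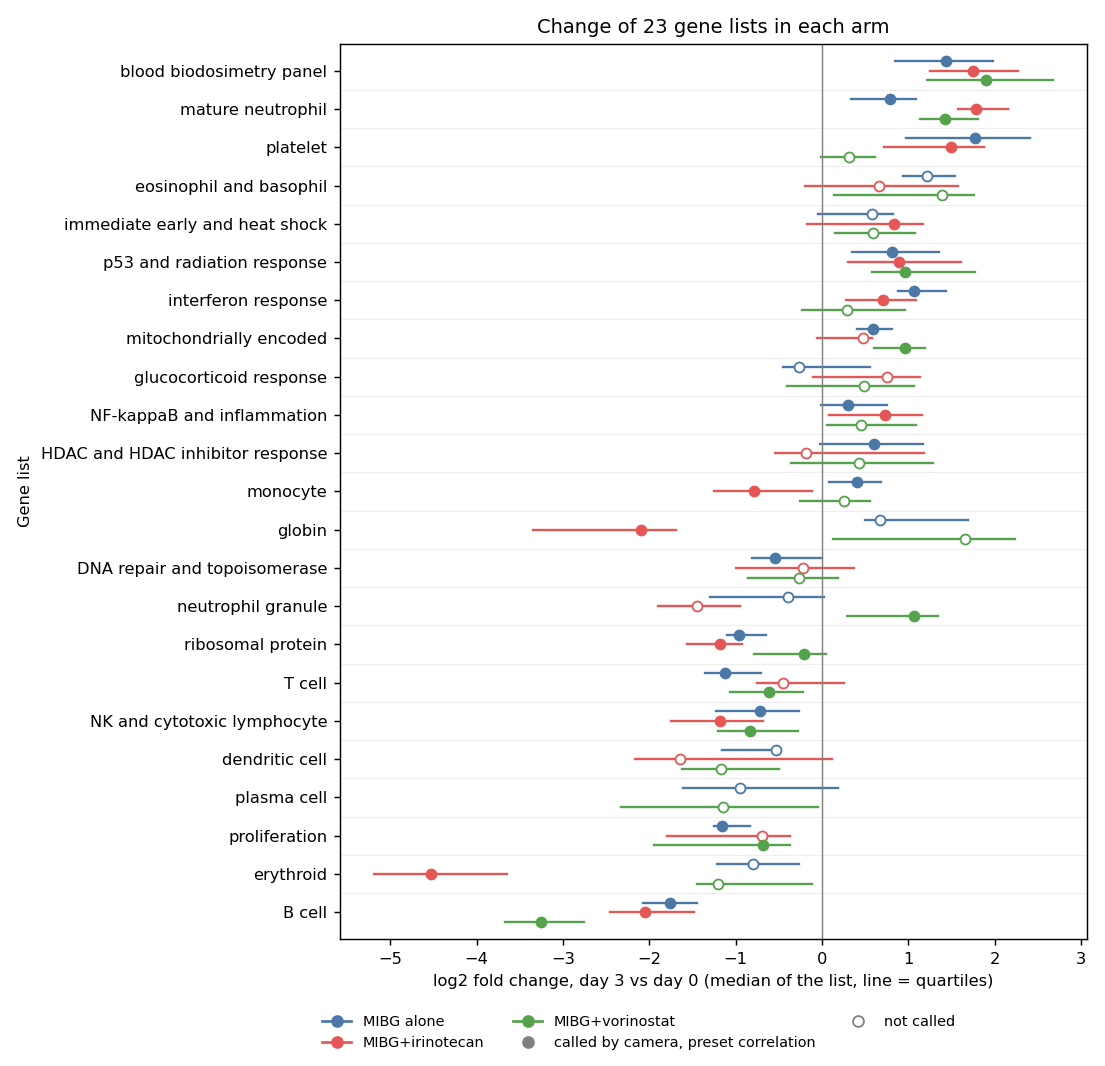
Median log2 fold change (day 3 over day 0, horizontal axis) of each gene list in each arm, with bars for the quartiles over the list's genes and filled points for lists called by camera with its preset correlation. Erythroid genes had a median of -4.53 with irinotecan, against -0.79 with MIBG alone and -1.21 with vorinostat.

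The arms were then compared with each other, for whether the added drugs changed the response. Erythroid genes stood higher at day 0 and lower at day 3 in the irinotecan arm than in the others. Their mean log2 level per library was 8.63 ± 1.05 at day 0 and 4.32 ± 0.89 at day 3 with irinotecan (SD, n = 5 per day). It was 6.16 ± 1.61 and 6.03 ± 1.08 with MIBG alone, and 6.57 ± 1.86 and 5.90 ± 1.62 with vorinostat. The day 0 level with irinotecan lay 2.27 above the other 2 arms (exact permutation p = 0.0183), so part of the -3.91 by which its change differed from theirs lay in the start. The change was lower than with MIBG alone in 30 of 30 members, with a median log2 difference of -3.48 (camera adjusted p = 1.14e-29, adjusted p = 0.289 with an estimated correlation and 0.0474 with the block added), and 23 passed adjusted over the list alone. With the block 27 passed over all genes, against 0 without it. The difference was -6.67 for SELENBP1 (95% interval -9.84 to -3.51, edgeR adjusted p = 0.214, blocked 3.71e-07), -4.75 for AHSP (-7.60 to -1.90, adjusted p = 0.281, blocked 6.62e-05) and -5.41 for EPB42 (-8.10 to -2.72, adjusted p = 0.214, blocked 2.12e-06). These 3 genes were chosen after their values were seen. By the rule fixed in advance, LYL1, a blood transcription factor, differed by -3.40 (adjusted p = 0.214, blocked 3.75e-06) and GALNT6, a glycosyltransferase, by -3.09 (adjusted p = 0.168, blocked 0.00329). Globin genes (-3.47, 7 of 8 adjusted over the list alone, and 0 over all genes or 7 with the block) and monocyte genes (-1.24, 1 of 17 adjusted over the list alone and 0 over all genes, 9 and 2 with the block) were called lower, and mature neutrophil genes (1.17, 0 of 20) higher, at adjusted p = 3.28e-06, 9.11e-07 and 9.98e-05. With an estimated correlation these were 0.373, 0.373 and 0.923. The neutrophil call was lost without MIBG alone day 0 replicate 5 (0.0784), and the block added the T cell list (0.0289). By edgeR 0 of 13286 genes passed (lowest adjusted p = 0.168), with 1114 at an unadjusted p under 0.05. DESeq2 called 44, voom 0, and edgeR with the donor block 271, of which 261 had the lower change in irinotecan. Without MIBG alone day 0 replicate 4 edgeR called 87.

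Vorinostat was set against irinotecan in the same way. Erythroid genes had the higher change with vorinostat in 30 of 30 members, with a median difference of 3.13 (camera adjusted p = 1.9e-23, adjusted p = 0.439 with an estimated correlation and 0.0797 with the block added), and 20 passed adjusted over the list alone. Over all genes 0 passed, and 24 with the block. IFIT1B differed by 7.88 (95% interval 4.46 to 11.3, edgeR adjusted p = 0.138, blocked 3.8e-07), PLEK2 by 7.53 (adjusted p = 0.138, blocked 0.000745) and UROD, an enzyme of haem synthesis, by 3.14 (adjusted p = 0.138, blocked 0.000154). Globin (3.74), monocyte (0.87), neutrophil granule (1.87) and ribosomal protein genes (0.93) were called higher, and platelet (-1.05) and B cell genes (-1.54) lower. Their adjusted p were 7.06e-06, 0.00489, 0.00489, 0.0238, 2.71e-05 and 0.00533, with 0.439 for globin and 0.916 for the others with an estimated correlation. Single libraries ended the calls of B cell genes (irinotecan day 0 replicate 4 or day 3 replicate 5, up to 0.232), neutrophil granule genes (irinotecan day 0 replicate 3, 0.136) and ribosomal protein genes (8 libraries, up to 0.412). The block added mature neutrophil (0.0389), interferon (0.0275) and mitochondrial genes (0.0432). By edgeR 0 genes passed (lowest adjusted p = 0.138), with 1035 at an unadjusted p under 0.05, against 44 by DESeq2, 0 by voom and 218 with the block, 205 of them higher with vorinostat. Without 1 library the count was 7 (MIBG alone day 0 replicate 4), 4 (irinotecan day 3 replicate 5), 97 (vorinostat day 0 replicate 5) or 8 (vorinostat day 3 replicate 2).

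Vorinostat was then set against MIBG alone. Platelet genes had the lower change with vorinostat (median -1.40, 24 of 25 lower, 1 adjusted over the list alone, 8 with the block, camera adjusted p = 2.13e-07, adjusted p = 0.834 with an estimated correlation). MYL9, a myosin light chain of platelets and smooth muscle, differed by -4.30 (95% interval -6.88 to -1.72, edgeR adjusted p = 1). Camera also called B cell (-1.56), interferon (-0.86) and monocyte genes (-0.20) lower, and neutrophil granule (1.23) and mature neutrophil genes (0.71) higher, at 0.00298, 0.00142, 0.0104, 0.000556 and 0.0217. Each was 0.834 with an estimated correlation, and 0.866 for mature neutrophil genes. Calls were lost without 1 library for B cell genes (MIBG alone day 0 replicate 2 or day 3 replicate 3, vorinostat day 0 replicate 4, up to 0.372), interferon genes (MIBG alone day 0 replicates 3 or 5, day 3 replicates 1 or 2, up to 0.39), neutrophil granule genes (MIBG alone day 0 replicate 2, 0.119), monocyte genes (7 libraries, up to 0.215) and mature neutrophil genes (7 libraries, up to 0.978). By edgeR 0 genes passed, with 226 at an unadjusted p under 0.05, and DESeq2, voom and the block called 0 each. The block added the erythroid list (0.00119).

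The panel and p53 lists were not called in any difference between arms. For CDKN1A the difference was -0.65 (95% interval -1.87 to 0.57, edgeR adjusted p = 0.836) for irinotecan against MIBG alone, -0.22 (-1.45 to 1.01, adjusted p = 1) for vorinostat against MIBG alone and 0.43 (-0.79 to 1.65, adjusted p = 0.945) for vorinostat against irinotecan. For FDXR these were 0.31 (-1.63 to 2.25), 1.08 (-0.87 to 3.03) and 0.77 (-1.22 to 2.75). Each interval reached beyond 2-fold in at least 1 direction. The interval of BBC3 for vorinostat against MIBG alone left out 0 (difference 1.01, 0.07 to 1.95, adjusted p = 1). VWCE, of the p53 list, differed by -3.82 for irinotecan against MIBG alone (adjusted p = 0.471, blocked 0.000879) and by 4.08 for vorinostat against irinotecan (adjusted p = 0.449, blocked 0.000352). VWCE was chosen after its values were seen. Irinotecan and vorinostat shared 424 genes that rose and 96 that fell, where independent lists would share 64.6 and 30.4, and 0 genes went opposite ways. With the donor block they shared 637 and 259, where independent lists would share 123 and 75.1, and 25 genes went opposite ways. Their log2 changes correlated at r = 0.584 across 9879 genes, against 0.54 for irinotecan and 0.705 for vorinostat with MIBG alone. Genes are not independent replicates, and the arms share no libraries.

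**Figure D3:**
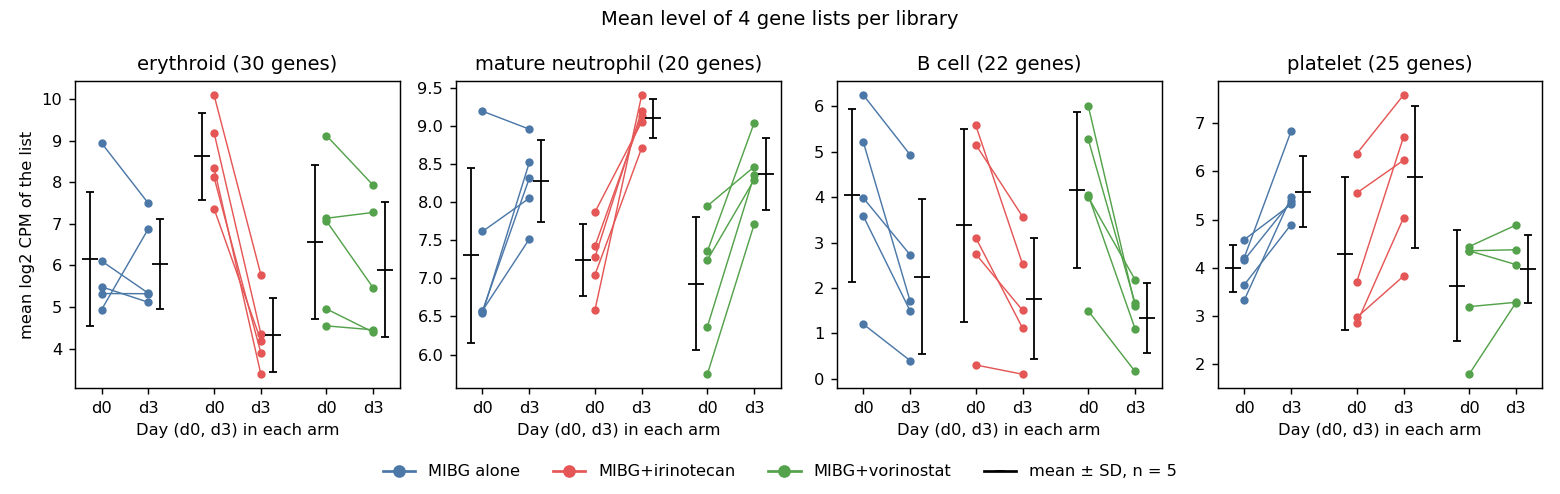
Mean log2 CPM (vertical axis) of the erythroid (30), mature neutrophil (20), B cell (22) and platelet (25) genes in each library, by arm and day (horizontal axis), with lines joining the libraries of 1 donor. Erythroid genes had a median log2 change of -4.53 over genes in the irinotecan arm.

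The last comparison looked for differences among the arms at day 0, before treatment. The genes with the smallest p were FBXO9, FLCN, IBA57, LYL1, OAZ2 and PRR5, each with an adjusted p of 0.625. Of 13286 genes 0 passed the edgeR F test, with 508 at an unadjusted p under 0.05, and DESeq2 called 1 and voom 6. Without MIBG alone day 0 replicate 4 edgeR called 1. The mean erythroid level was 2.27 higher on the log2 scale with irinotecan than in the other 2 arms at day 0 (exact permutation p = 0.0183), in a test chosen after the results were seen. LYL1 was also among the genes with the smallest p for irinotecan against MIBG alone.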

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

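The 3 tests of the erythroid pattern, the test of depth and the list tests of differences between arms were chosen after the results, or single genes that bear on them, had been seen. Among 114 sets of 5 libraries, 7 had a library far from the others, where chance alone gives about 5.7. The gap to the nearest library, as a share of the range, was 0.764 for the globin share of MIBG alone day 0 replicate 4 (15.12% of counts), 0.818 for vorinostat day 0 replicate 5 (19.9%) and 0.787 for vorinostat day 3 replicate 5 (38.06%). For the share of the 10 highest genes it was 0.821 in vorinostat day 0 replicate 5 (28.65%) and 0.857 in day 3 replicate 5 (46.59%). For the log2 level of DDB2 it was 0.729 in vorinostat day 3 replicate 4, and for PHPT1 0.782 in vorinostat day 0 replicate 5.

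Lists differed between arms by camera with its preset correlation, and none with an estimated correlation in the fit without the block. For irinotecan against MIBG alone the adjusted p was 1.14e-29 for erythroid, 9.11e-07 for monocyte, 3.28e-06 for globin and 9.98e-05 for mature neutrophil genes. For vorinostat against MIBG alone it was 2.13e-07 for platelet, 0.000556 for neutrophil granule, 0.00142 for interferon, 0.00298 for B cell, 0.0104 for monocyte and 0.0217 for mature neutrophil genes. For vorinostat against irinotecan it was 1.9e-23 for erythroid, 7.06e-06 for globin, 2.71e-05 for platelet, 0.00489 for monocyte and for neutrophil granule, 0.00533 for B cell and 0.0238 for ribosomal protein genes. With the donor block 271 genes differed for irinotecan against MIBG alone and 218 for vorinostat against irinotecan.

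Other splits of the same libraries were fitted in the same way. Day splits gave as many genes as the real one in 4 of 100 for MIBG alone (1 gene, highest other 263). For irinotecan it was 1 of 100 (1755, highest other 6) and for vorinostat 1 of 100 (1065, highest other 49). For all arms it was 1 of 60 (3792, highest other 1). These shares argue against chance for irinotecan, vorinostat and all arms, in splits that leave the pairing out. For MIBG alone chance is left open, since the count is 1 gene and 3 other splits gave as many or more. The split with 263 genes points to a structure of the samples, and what made it was not tested. The 16 splits of an arm that part all 5 pairs are too few for a share under 0.05. Among them no other split called a gene, and those of MIBG alone with the block gave 381 for the real days and 0 for the others. For lists the shares were 3 of 100 for MIBG alone (15 lists, highest other 15), 3 of 100 for irinotecan (13, highest other 14), 30 of 100 for vorinostat (10, highest other 16) and 1 of 60 for all arms (17, highest other 12), so chance cannot be excluded for the number of lists with vorinostat. The median of the other splits was 9, 8, 8 and 9 lists in the same order, so many lists were called without the real days. Other splits that part all pairs gave up to 15, 13 and 12 lists in the arms, as many as the real days or more, and up to 16 over all arms. So chance is left open for the number of lists with MIBG alone and irinotecan too. For all arms no other split reached 17 lists, but up to 16 in the splits that part all pairs is too close to exclude chance. With donors dealt to other arms, differences in genes were 0 in the real arms and up to 0 in 40 of 40 splits each. The day 0 test gave 0 against up to 2 in 40 of 40. Any split reaches a real count of 0, so for genes these splits can decide nothing. Differences in lists were as many in 26 (4 lists, highest other 12), 16 (6, highest other 11) and 9 (7, highest other 11) of 40 splits, so chance cannot be excluded for these numbers. The median of the other splits was 4, 5 and 4 lists. With the block, 271 and 218 genes were reached in 1 of 30 splits each, the real one (highest other 0 and 2). That argues against chance as far as 30 splits can. Both differences hold the irinotecan donors, so they are not independent of each other, and those donors stood apart in erythroid level at day 0. As many lists came in 23 (5 lists, highest other 14) and 3 of 30 (10, highest other 11).

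Erythroid genes had a lower change in the irinotecan arm by camera with its preset correlation, and this was set against 2 technical explanations. With globin, mitochondrial and ribosomal protein genes left out before scaling, the median difference from MIBG alone was -3.43, against -3.48 with them, which argues against globin counts and scaling. At day 0 the erythroid level of that arm stood 2.27 above the other 10 libraries on the log2 scale (exact permutation p = 0.0183), and at day 3 it stood at -1.64 relative to them (exact permutation p = 0.027), so a higher starting level is not the whole of it, while it may be part. The change of 5 of 5 irinotecan donors lay below that of every other donor. That follows from the pattern and the start as well, so it cannot tell whether the drugs had an effect. Donors and drugs differ together between arms, and earlier treatment and transfusion were not tested, so an effect of the drugs stays open.

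By edgeR 1 gene passed with MIBG alone, against 1755 with irinotecan and 1065 with vorinostat, with 1621 at an unadjusted p under 0.05, 314 called by DESeq2 and 381 with the donor block. The median standard error was 0.466 with MIBG alone, 0.487 with irinotecan and 0.441 with vorinostat, and 0.408, 0.442 and 0.416 with the donor block, and the ratio of 0.959 to the larger of the first values argues against a larger spread than with irinotecan. A larger spread than with vorinostat is left open without the block and not seen with it, while a mean total count 1.04 of the lower of theirs argues against lower depth. Over 1042 genes called with vorinostat and tested in all arms, the median change with MIBG alone was 0.794 of that with irinotecan, and 99.1% had the sign seen with vorinostat. A somewhat weaker change may play a part, and that ratio lay between the bounds set for and against it, with no test of the number of responding genes between arms.

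Ribosomal protein genes stood lower at day 3 across the arms, with a median of -0.82. The 192 genes matched to them on transcript length and level had a median of 0.39 (quartiles -0.16 and 0.91), the other way, which argues against an effect of short transcripts. A lower share of lymphocytes, rich in these transcripts, could account for it. In the 1 relation computed, over 15 donors, the changes of the ribosomal protein and T cell scores had Pearson r = 0.273 (permutation p = 0.326) and Spearman rho = 0.157 (permutation p = 0.576), with r = -0.108 without the 2 donors farthest from the median and 0.362 within arms. That leaves it open, and no explanation by the arms was tested.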

How the results depend on the processing

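The settings without 3 libraries, the block joined with an estimated correlation, and the list tests of the differences between arms were chosen after the results were seen. Counts of genes that passed by edgeR moved by more than 1.5 times under the following settings, and the cause was not tested. For MIBG alone (1 gene), the count was 375 without a filter, 314 by DESeq2, 37 by voom, 381 with the replicate block and 17 in 1 fit over 30 libraries. For vorinostat (1065) it was 1876 by DESeq2 and 1815 by voom. For irinotecan minus MIBG alone (0, with 1114 at an unadjusted p under 0.05) it was 271 without a filter, 44 by DESeq2 and 271 with the block. For vorinostat minus MIBG alone (0, with 226) it was 5 without a filter. For vorinostat minus irinotecan (0, with 1035) it was 279 without a filter, 44 by DESeq2 and 218 with the block. For the arms at day 0 (0, with 508) it was 281 without a filter, 1 by DESeq2 and 6 by voom. In simulated counts DESeq2 called more unchanged genes than edgeR, so its larger counts carry more error. Counts for irinotecan and for all arms together stayed within 1.5 times of 1755 and 3792 under each setting run.

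Lists called by camera numbered 15, 13, 10 and 17 for MIBG alone, irinotecan, vorinostat and all arms, and 4, 6 and 7 for the differences irinotecan minus MIBG alone, vorinostat minus MIBG alone and vorinostat minus irinotecan. With an estimated correlation these became 2, 1, 2, 3, 0, 0 and 0, and with the block added to that 0, 0, 0, 2, 1, 0 and 0. Fry called 8, 13, 7 and 18 lists for MIBG alone, irinotecan, vorinostat and all arms, and 0 for each difference without the block. Of these, 7, 10, 4 and 15 had been called by camera in the same direction. With irinotecan they included erythroid and mature neutrophil genes (fry adjusted p = 0.000363 each). With vorinostat they were the panel, p53, B cell (fry adjusted p = 0.0283) and mature neutrophil lists (0.0279). With the block, fry called erythroid (adjusted p = 0.000281), globin (0.00177), monocyte (0.0386) and HDAC genes (0.0386) for irinotecan minus MIBG alone. For vorinostat minus irinotecan it called erythroid (0.00097) and globin genes (0.00202). No list passed so for vorinostat minus MIBG alone (lowest adjusted p = 0.369).

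Without 1 library, the counts of genes ranged from 1 to 5 (highest without day 0 replicate 5) for MIBG alone, 436 to 1045 (lowest without day 0 replicate 4) for vorinostat, 0 to 87 (MIBG alone day 0 replicate 4) for irinotecan minus MIBG alone, 0 to 97 (vorinostat day 0 replicate 5) for vorinostat minus irinotecan, and 0 to 1 (MIBG alone day 0 replicate 4) at day 0. For irinotecan they ranged from 1316 to 1762 and for all arms from 3426 to 4163. Lists ranged from 8 to 16 for vorinostat (highest without day 0 replicate 5) and from 3 to 8 for vorinostat minus MIBG alone (lowest without MIBG alone day 0 replicate 2 or day 3 replicate 2). Without the 3 libraries with the most extreme globin counts or scaling, 1, 1627, 1045 and 3405 genes passed in the 4 tests of day 3, 0 in each difference and 0 at day 0.

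Directions turned for genes that had not passed. PCNA with MIBG alone, with a log2 change of -0.02, was 0.009149 with DESeq2's factors, 0.01791 without a filter, 0.009075 by DESeq2, 0.1671 with the block, 0.1025 without the 3 libraries, and -0.2785 to 0.2014 without 1 library. PCNA with vorinostat was 0.02668 without the 3 libraries and -0.3532 to 0.1037 without 1. Without 1 library PHPT1 with MIBG alone was -0.0799 to 0.5911. Among differences without 1 library, FDXR was -0.02799 to 1.321 for irinotecan minus MIBG alone and -0.2419 to 1.13 for vorinostat minus irinotecan, and CDKN1A was -0.6633 to 0.002508 for vorinostat minus MIBG alone. CDKN1A was -0.09625 for vorinostat minus irinotecan without the 3 libraries. Of 215 named results, 170 kept direction and side of the threshold by DESeq2, 194 by voom, 213 with DESeq2's factors and 161 without a filter, as did 162 of 209 with the block. Lists whose call the block changed are given with the result. Of the genes chosen by the rule not all are described. With MIBG alone 21 of 37 of these genes passed with the block and not without it. Genes with too few counts, such as those of the neuroblastoma list, were left out of the tests, and whether depth or their level in blood caused this was not tested.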

Other observations

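The genes in this part were chosen by the rule fixed in advance, and no test here was chosen after a result was seen. Over the 3 arms together, several lineage genes not described above changed between day 0 and day 3. CD8A, a coreceptor of cytotoxic T cells, fell 2.49-fold (edgeR adjusted p = 0.00121), with 88.6 ± 55.3 CPM at day 0 and 36.8 ± 20.7 CPM at day 3 (SD, n = 15 per day). KLRB1, a receptor of NK and some T cells, fell 3.51-fold (adjusted p = 0.000169), and POU2AF1, a coactivator in B cells, 5.91-fold (adjusted p = 0.000373). FECH, which inserts iron into haem, fell 7.92-fold (adjusted p = 0.000478) and BPGM, a red cell enzyme, 8.39-fold (adjusted p = 0.000561). The log2 change of FECH was -5.02 with irinotecan (adjusted p = 0.000423), -1.79 with MIBG alone (adjusted p = 0.309, blocked 0.174) and -2.37 with vorinostat (adjusted p = 0.153, blocked 0.00648). That of BPGM was -5.66 (adjusted p = 0.000432), -1.90 (adjusted p = 0.298, blocked 0.476) and -2.11 (adjusted p = 0.148, blocked 0.0202). CDK1, a kinase of the cell cycle, fell 13.3-fold (adjusted p = 0.00131), and RPA1, which binds single-stranded DNA, 2.25-fold (adjusted p = 0.000363). IL1RN, an antagonist of interleukin 1, rose 2.52-fold (adjusted p = 0.00133), higher at day 3 in 14 of 15 donors. MX2, induced by interferon, rose 2.38-fold (adjusted p = 9.8e-05), higher in 15 of 15. ITGA2B, a subunit of the platelet fibrinogen receptor, rose 3.75-fold (adjusted p = 0.00263), higher in 13 of 15.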
